A study of Mus musculus with 20 samples.

How the data were processed

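The series holds 20 mouse samples, 1 array each: 6 CDS tumors, 6 ES tumors, 4 samples of eMC transduced with CIC-DUX4 and 4 of eMC with the empty vector. Total RNA had been labelled with biotin and hybridised to Affymetrix mouse arrays of perfect-match probes. The deposited values are log2 signals, for which the submitters' processing notes name MAS5; its version, background method and scaling settings are not given in the sources used here. On the linear scale the 2% trimmed mean of each deposited array is nearly the same, 499.914 to 499.966, the arrays' quantiles differ, and between 0.0111% and 5.00% of an array's values are exactly 0. The analysis had been laid out for linear signals with a return to the linear scale if the values proved to be log2, and that was done. There were 0 columns of no listed sample and 0 arrays holding identical values.

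Of the 45141 probe sets, 104 controls were left out. Of the other 45037, 28898 had 1 gene symbol in the gene table of the array, 551 several and 15588 none; 28689 of those with 1 symbol matched a gene of the reference by Entrez number, and 0 symbols were updated. Linear signals entered as log2(signal + 1.42305), the offset being 0.25 of the median of the array medians (5.6922). A probe set was kept if it exceeded its array's median in at least 4 of the 20 arrays: 26897 passed, 19542 of them with 1 symbol, for 12343 genes. Each gene was tested with its probe set of the highest mean over all arrays. The precision is limited by the number of arrays.

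The 4 comparisons (eMC CIC-DUX4 against eMC empty; CDS tumors against eMC empty, ES tumors and eMC CIC-DUX4) were each fitted on their 2 groups with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 with data.table, version 1.17.8. All tests are two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Because the arrays' distributions differ, each fold change is printed as deposited and, as "quantile", after quantile normalization of the log2 values; values "above all genes" or "against all genes" are the deposited fold change minus the median of all genes tested. For called genes, where every array of the dimmer group had a dip and lay below it (the lowest density between the dim and the bright part, bandwidth 0.35), the fold is given as "at least": the mean of the brighter group against the mean over the dimmer arrays of the higher of the dip and the signal; no fold is given where it was under 1. The array eMC CIC-DUX4 6 had no dip. The log2 fold changes printed beside a bound are those of the fit and rest on signals below the dip. The bounds hold for the deposited signals only, and some quantile values lie below them. Array measures were compared by exact permutation tests.

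There were 24 gene lists with 377 members, 330 on the array and 283 tested; lists with fewer than 3 measured members (2 lists) were described only. The lists were CIC target genes, DUX4 and Dux cleavage-stage genes, Ewing sarcoma markers and EWS-FLI1 targets, cell cycle and DNA replication, MAPK immediate-early genes, collagen and extracellular matrix, smooth muscle and myofibroblast, cartilage, bone, neural and neuroendocrine, Wnt pathway, interferon response, p53 targets, hypoxia and glycolysis, stress response, and markers of endothelium, pericytes, macrophages, lymphocytes, neutrophils, erythroid cells, skeletal muscle, keratinocytes and adipocytes. Lists were tested against all other genes with limma camera at a preset correlation of 0.01, adjusted over the lists, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

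The genes named are, in each comparison, the 8 highest and 8 lowest fold changes (5 and 5 for CDS tumors against eMC CIC-DUX4) among called genes whose values do not overlap between the groups, without predicted or clone-derived names; 11 genes of interest (Cic, Etv1, Etv4, Etv5, Ccnd1, Ccnd2, Muc5ac, Fli1, Erg, Ewsr1, Nkx2-2); and up to 4 called members of each list with the largest absolute fold change, or 2 with the highest mean where 0 were called. Lists, comparisons, filter, offset, thresholds, tests and this rule were chosen before the data were examined. The probe sets of Mycn, the genes higher in 3 comparisons and the use of the dip were chosen after seeing the data. Counts of named genes under other settings leave out members of lists not called as deposited, unless named for another reason.

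Alternatives were another offset, filter, scaling, spread model, summary of probe sets, threshold, set test, the replicate number as a block, each array left out in turn, and, chosen after seeing the data, the 3 arrays with a median log2 signal over 5 left out. The steps were tested on simulated data. Overlaps were tested with Fisher's exact test where no arrays were shared; for shared controls, unchanged groups were simulated 100 times. Probe sets with no or several gene symbols were not used for gene counts. Raw probe intensities were not used here.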

Results

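Gene expression was measured on 20 Affymetrix mouse arrays of perfect-match probes, each hybridised with labelled RNA of 1 sample. The samples form 4 groups. CDS tumors (6 arrays) are sarcomas that grew under the skin of nude mice from embryonic mesenchymal cells carrying CIC-DUX4, a fusion of the transcriptional repressor CIC with the transcription factor DUX4. ES tumors (6 arrays) are mouse tumors of another type that were profiled for comparison. Embryonic mesenchymal cells (eMC) were collected in culture 48 hours after retroviral transduction with CIC-DUX4 (eMC CIC-DUX4, 4 arrays) or with an empty vector (eMC empty, 4 arrays). Every array held 45141 probe sets, and the number of arrays limits the precision of each value. The CDS tumors were individual tumors. The labels do not say whether the eMC arrays came from separate cultures, so p-values measure only the spread between samples.

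The arrays had been brought to the same trimmed mean, 499.914 to 499.966 on the linear scale, but their distributions differed. The 75th percentile of the log2 signal ranged from 4.10 to 8.94. It was higher in all 4 eMC CIC-DUX4 arrays (mean 8.77) than in all 4 eMC empty arrays (mean 5.07). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays allow, and 0.0508 when adjusted over 16 such comparisons. An array's distribution has a dip between its dim and its bright part. The share of probe sets above the dip was 17.9 ± 6.91% (SD, n = 4) in eMC empty, 31.6 ± 17.1% (n = 6) in CDS tumors and 34.2 ± 4.76% (n = 6) in ES tumors. It was 51.1 ± 17.8% in the 3 eMC CIC-DUX4 arrays with a dip, and replicate 6 had none.

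The median change of all genes tested was 2.07 (log2) in eMC CIC-DUX4 against eMC empty and 0.89 in CDS tumors against eMC empty. It was 0.02 in CDS against ES tumors and -0.92 in CDS tumors against eMC CIC-DUX4. After quantile normalization these 4 medians were 0.01, -0.10, -0.03 and -0.06, and changes are given on both scales. With each array scaled to the same median they were 0.49, 0.14, -1.11 and -0.09. CDS tumor 2 and eMC CIC-DUX4 5 and 6 had a median log2 signal over 5. Counts without these 3 arrays are given where they differ by over 1.5 times. The excess of 3′ over 5′ signal of Actb, a sign of RNA degradation, was 0.80 ± 0.36 log2 in CDS tumors (SD, n = 6) and 0.25 ± 0.05 in ES tumors (n = 6). This difference had an exact permutation p of 0.00216 (adjusted 0.0173). The excess was 0.22 ± 0.02 in eMC CIC-DUX4 and 0.17 ± 0.03 in eMC empty (n = 4 each).

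**Figure D1:**
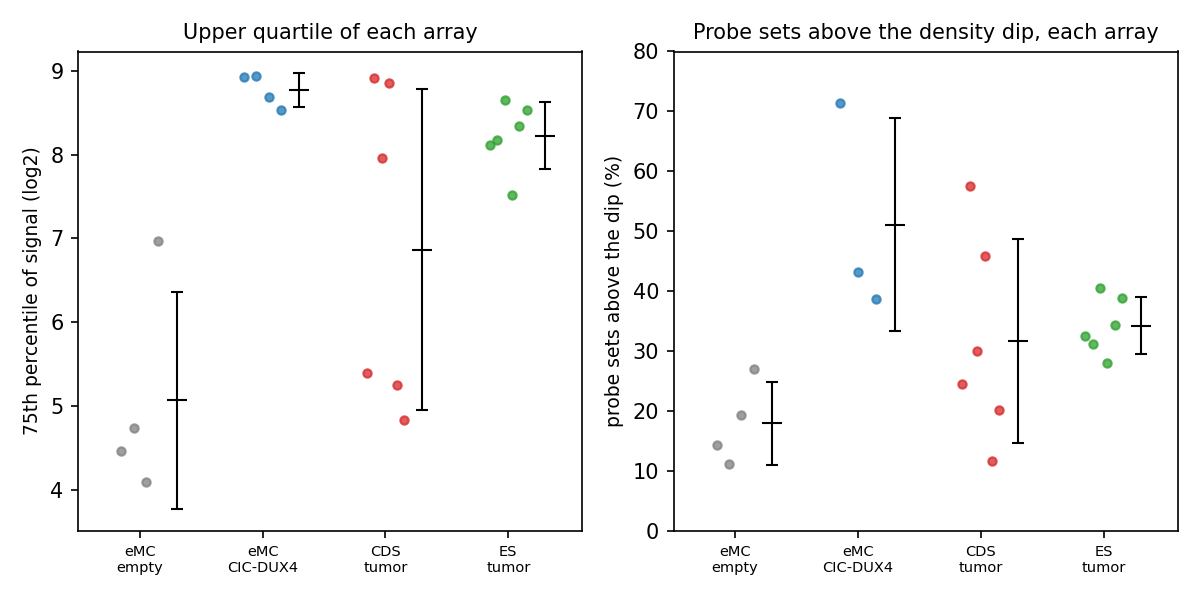
For each array, the left panel plots the 75th percentile of the log2 signal and the right panel the percentage of probe sets above the density dip, by group, with mean ± SD beside the points. The 4 eMC CIC-DUX4 arrays lie above the 4 eMC empty arrays in the left panel (means 8.77 and 5.07); in the right panel eMC CIC-DUX4 has 3 arrays.

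The comparison of eMC CIC-DUX4 with eMC empty asked which genes had changed within 48 hours of transduction. Vgf, which encodes a secreted neuropeptide precursor, was at least 13.9-fold higher in eMC CIC-DUX4, with a mean log2 signal of 10.64 ± 0.27 (SD, n = 4) against 2.89 ± 0.25 (n = 4). Its log2 fold change was 7.75 ± 0.31 (SE), which is 5.68 above the median of all genes, and 7.09 ± 0.21 after quantile normalization. The ETS transcription factors Etv1 and Etv5, repressed by CIC in normal cells, rose as well. Etv1 was at least 4.01-fold higher (5.12 ± 0.34, 3.05 above all genes, quantile 2.00 ± 0.19) and Etv5 rose by 5.32 ± 0.65 (3.25 above all genes, quantile 2.87 ± 0.12).

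Of the other genes with the highest fold changes, Pappa2, a protease of insulin-like growth factor binding proteins, was at least 10.8-fold higher (6.75 ± 0.32, quantile 4.79 ± 0.17). Dkk2, a secreted Wnt pathway regulator, was at least 12.1-fold higher (6.39 ± 0.30, quantile 3.72 ± 0.17) and Bmp2, a bone morphogenetic protein, at least 6.66-fold (6.15 ± 0.33, quantile 3.99 ± 0.21). Cxcl13, a B cell chemokine, was at least 8.99-fold higher (6.10 ± 0.32, quantile 3.31 ± 0.18). Clec7a, Enpep and Nt5e were at least 11.9-fold, 14.1-fold and 7.36-fold higher (6.39, 6.38 and 6.21, quantile 3.68, 3.63 and 3.96). These 7 genes were below the dip in every eMC empty array.

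In the other direction, a probe set of Mycn, the N-myc transcription factor, fell from 14.31 ± 0.35 (SD, n = 4) in eMC empty to 7.25 ± 0.97 (n = 4) in eMC CIC-DUX4. Its log2 fold change was -7.06 ± 0.46 (SE), -9.14 against all genes and -8.47 ± 0.12 after quantile normalization. The other 2 probe sets of Mycn had means of 2.33 and 2.66 in eMC empty and of 3.90 and 4.39 in eMC CIC-DUX4. The mean of all 3 gave a change of -1.25 with an adjusted p of 0.193. Saa3, an acute-phase protein, changed by -3.22 ± 0.16 (quantile -2.65 ± 0.04), and the chemokine genes Cxcl1 by -2.18 ± 0.19 (quantile -2.39), Ccl2 by -2.08 ± 0.17 (quantile -1.06) and Ccl7 by -2.06 ± 0.15 (quantile -1.44). Hp, the haemoglobin-binding haptoglobin, changed by -2.06 ± 0.19 (quantile -1.83). Mt1, a metal-binding metallothionein, changed by -2.31 ± 0.17 (quantile -1.38) and Mylpf, a fast muscle myosin light chain, by -1.96 ± 0.18 (quantile -2.01 ± 0.14). Adjusted p (limma, Benjamini-Hochberg) was 8.28e-06 for Vgf, Etv1, Mycn and Saa3 and 0.000112 for Etv5. With all 4 groups in the same fit, the adjusted p was 0.0573 for Saa3, 0.0736 for Cxcl1 and 0.433 for Mylpf. Scaling each array to the same median moves the bright part of the eMC CIC-DUX4 arrays apart (medians 1.85 to 7.03, 75th percentiles 8.53 to 8.94). It ended the calls of 49 of the 57 genes named in this comparison. Adjusted p was 0.0628 for Vgf, 0.187 for Etv1, 0.207 for Etv5 and 0.161 for Saa3. Of the 57, only Mycn (0.00730) and the cartilage gene Matn1 (0.0425) remained called. The 57 include Etv4, Muc5ac, Erg, Ccnd1, Ccnd2 and Ewsr1, which had no call as deposited to lose.

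Of the other genes of interest named in advance, Cic rose by 3.84 ± 0.62 (adjusted p = 0.000632), and was not called after quantile normalization (0.35 ± 0.13). Fli1 was at least 1.88-fold higher as deposited (3.85 ± 0.43), a bound that does not hold after quantile normalization, where it turned to -0.16. Etv4 (0.66 ± 1.32), Muc5ac (1.66 ± 1.15) and Erg (0.71 ± 1.28) were not called. For Etv4 and Erg the positive sign rests on eMC CIC-DUX4 6, with signals of 6.06 and 6.71. The other arrays of that group (1.56 to 1.69 and 1.73 to 2.05) lay below the eMC empty means of 2.07 and 2.37. Ccnd1 (-0.63 ± 0.15), Ccnd2 (-0.89 ± 0.16) and Ewsr1 (-0.61 ± 0.16) were not called either, and had the other sign after quantile normalization (0.22, 0.02 and 0.06). Of the probe sets of Ccnd2, 2 of 6 were called the other way.

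With the values as deposited, 6303 of 12343 genes were called, 5733 higher and 570 lower (91.0% higher). After quantile normalization 1590 were called, 996 higher and 594 lower (62.6% higher), and after scaling each array to the same median 20, of which 13 were higher (65.0%). The same call in the same direction on both the deposited and the quantile scale was made for 995 genes (948 higher, 47 lower), and opposite calls for 240. Of the 2566 called genes with several probe sets, 89 had another probe set called the other way.

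Of the 22 gene lists tested, all fixed before the data were examined, 8 were called as deposited and 11 after quantile normalization, 7 of them in the same direction on both scales and 1 in opposite directions. There were 5 without eMC empty 7, 5 without the 3 arrays of high median and 0 with an estimated correlation. The deposited directions may follow signal level. The 99th percentile was lower in eMC CIC-DUX4 (13.2 to 13.7) than in eMC empty (14.2 to 15.0), while the median change was 2.07. In eMC empty the mean signal was 4.87 for the cartilage list and 6.09 (muscle) to 13.08 (collagen) for the 7 lists called lower. The cartilage list lay above the other genes (limma camera, two-sided, adjusted p = 0.0104), but had adjusted p = 0.354 with an estimated correlation. It was 0.0550 without eMC empty 7, and 7.84e-06 after quantile normalization (adjusted p = 0.0716 with an estimated correlation on that scale). Of 15, 12 were called higher and 0 lower (12 also adjusted over the list alone, 11 after quantile normalization). Hapln1, a link protein of cartilage matrix, was at least 6.09-fold higher (5.90 ± 0.31, quantile 3.41 ± 0.19), and the matrilin genes Matn1 and Matn3 at least 2.00-fold and 2.77-fold (5.35 ± 0.42 and 4.59 ± 0.35, quantile 3.22 and 1.13). Sox9, the master regulator of cartilage formation, was at least 2.80-fold higher (4.83 ± 0.33, quantile 0.84, not called).

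Of the 18 CIC target genes 11 were called higher and 0 lower (11 adjusted over the list alone), and 3 higher and 2 lower after quantile normalization. Spry4, an inhibitor of growth factor signalling, rose by 3.90 ± 0.76 (quantile 0.80 ± 0.13, not called). As a group the CIC targets did not exceed the other genes as deposited (adjusted p = 0.681). After quantile normalization they did (0.0149, but adjusted p = 0.0819 with an estimated correlation). Of the Ewing sarcoma markers and EWS-FLI1 targets 9 of 19 were called higher and 1 lower (10 adjusted over the list alone), among them Prkcb, a protein kinase C, at least 5.54-fold (5.92, quantile 3.63). The Ewing sarcoma list had an adjusted p of 0.997, and of 0.0212 upward after quantile normalization (adjusted p = 0.0848 with an estimated correlation). Wnt pathway targets and antagonists gave 5 higher and 1 lower of 9 (6 adjusted over the list alone), with Nkd1, a feedback inhibitor, at least 3.24-fold higher (4.83 ± 0.32, quantile 1.52). The Wnt list had an adjusted p of 0.427, and of 0.0337 upward after quantile normalization (adjusted p = 0.105 with an estimated correlation).

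The cell cycle and DNA replication list lay below the other genes (adjusted p = 0.000555), although its own median and mean were positive, 0.31 and 0.65. It had adjusted p = 0.301 with an estimated correlation and 0.0680 without the 3 arrays of high median. After quantile normalization the list's adjusted p was 0.000930, and 0.0421 with an estimated correlation too. As deposited, 5 of its 29 genes were higher and 3 lower (8 adjusted over the list alone), and after quantile normalization 0 higher and 6 lower. E2f1, Ccne1 and Cdc45 were called higher as deposited and had values of -0.28, -1.13 and -0.92 after quantile normalization. Interferon response genes gave 3 higher and 3 lower of 11 (7 adjusted over the list alone), with a median of 0.72 and a mean of 0.62, and 7 lower after quantile normalization. Ifit1, an antiviral RNA-binding protein, changed by -1.66 ± 0.25 (quantile -2.70 ± 0.08), with an adjusted p of 0.184 when all 4 groups were in the same fit. The interferon list was below the other genes with an adjusted p of 0.0351 (adjusted p = 0.638 with an estimated correlation). After quantile normalization it was 1.39e-05 (adjusted p = 0.0421 with an estimated correlation on that scale). The call as deposited was lost without eMC empty 6 (0.0664) or 7 (0.138), and without the 3 arrays of high median (0.207).

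Skeletal muscle genes, markers of a host tissue, gave 3 higher and 4 lower of 14 (7 adjusted over the list alone), and 5 lower after quantile normalization. They had a median of 1.16 and a mean of 0.77 but a test below the other genes (adjusted p = 0.0351). The muscle list had adjusted p = 0.354 with an estimated correlation, 0.162 without eMC CIC-DUX4 8 and 0.241 with the replicate number as a block. After quantile normalization its adjusted p was 0.000328, and 0.0421 with an estimated correlation too. Hypoxia and glycolysis genes gave 6 higher and 5 lower of 19 (11 adjusted over the list alone). With a median of 0.33 and a mean of 0.83, they too tested below the other genes (adjusted p = 0.0104, and adjusted p = 0.194 with an estimated correlation). Without eMC empty 7 the hypoxia list had an adjusted p of 0.0550, and without the 3 arrays of high median 0.0800. Of its members, Aldoc, a glycolytic aldolase, was at least 2.51-fold higher (5.04 ± 0.34, quantile 2.48) and Vegfa, the main angiogenic growth factor, rose by 3.53 ± 0.87 (quantile 1.18 ± 0.10).

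Collagen and extracellular matrix genes were below the other genes as deposited (adjusted p = 3.12e-09, and adjusted p = 0.301 with an estimated correlation) and above them after quantile normalization (0.000738, and adjusted p = 0.0877 with an estimated correlation). As deposited 2 of 20 were higher and 8 lower (10 adjusted over the list alone), and after quantile normalization 2 higher and 0 lower. Col1a2, a chain of type I collagen, was called higher (3.79 ± 0.53, quantile 1.07 ± 0.29), but was below the dip in every eMC empty array and its mean in eMC CIC-DUX4 did not exceed the mean of those dips, so no fold is given. Timp1, an inhibitor of matrix proteases, changed by -1.48 ± 0.13 (quantile -0.62) and Col3a1, type III collagen, by -1.46 ± 0.18, which turned to 0.04 after quantile normalization. Smooth muscle and myofibroblast genes gave 2 higher and 4 lower of 12 (6 adjusted over the list alone), with a median of -0.40 and a mean of 0.10. The smooth muscle list was below the other genes with an adjusted p of 0.000204 (adjusted p = 0.194 with an estimated correlation). Acta2, smooth muscle actin, changed by -1.85 ± 0.18 (quantile -0.58). Genes of the cytosolic and endoplasmic reticulum stress response gave 2 higher and 4 lower of 11 (6 adjusted over the list alone). The stress list had an adjusted p of 0.000240 (adjusted p = 0.290 with an estimated correlation). The stress transcription factor Atf4 changed by -1.50 ± 0.17 (quantile -0.58) and the chaperone Hspa5 by -1.48 ± 0.18 (quantile -0.18).

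The remaining lists were not called. Higher were 7 of 13 MAPK immediate-early genes, 5 of 12 p53 targets, 2 of 5 bone and 6 of 12 neural and neuroendocrine genes. Adjusted over the list alone these were 7, 5, 1 and 2, and each list had an adjusted p of 0.997. Among markers of host cells, 6 of 14 endothelial (adjusted p = 0.407), 5 of 6 pericyte (0.339), 8 of 15 macrophage (0.997) and 2 of 4 lymphocyte genes (0.746) were higher. Neutrophils had 1 of 7 higher (0.997), keratinocytes 5 of 9 (0.407) and adipocytes 2 higher and 3 lower of 7 (0.0769). Each of these 7 host lists had as many called adjusted over the list alone. The MAPK, p53 and neutrophil lists tested below the other genes despite positive medians and means, and the adipocyte list with a negative median (-0.33) and a positive mean (0.45).

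**Figure D2:**
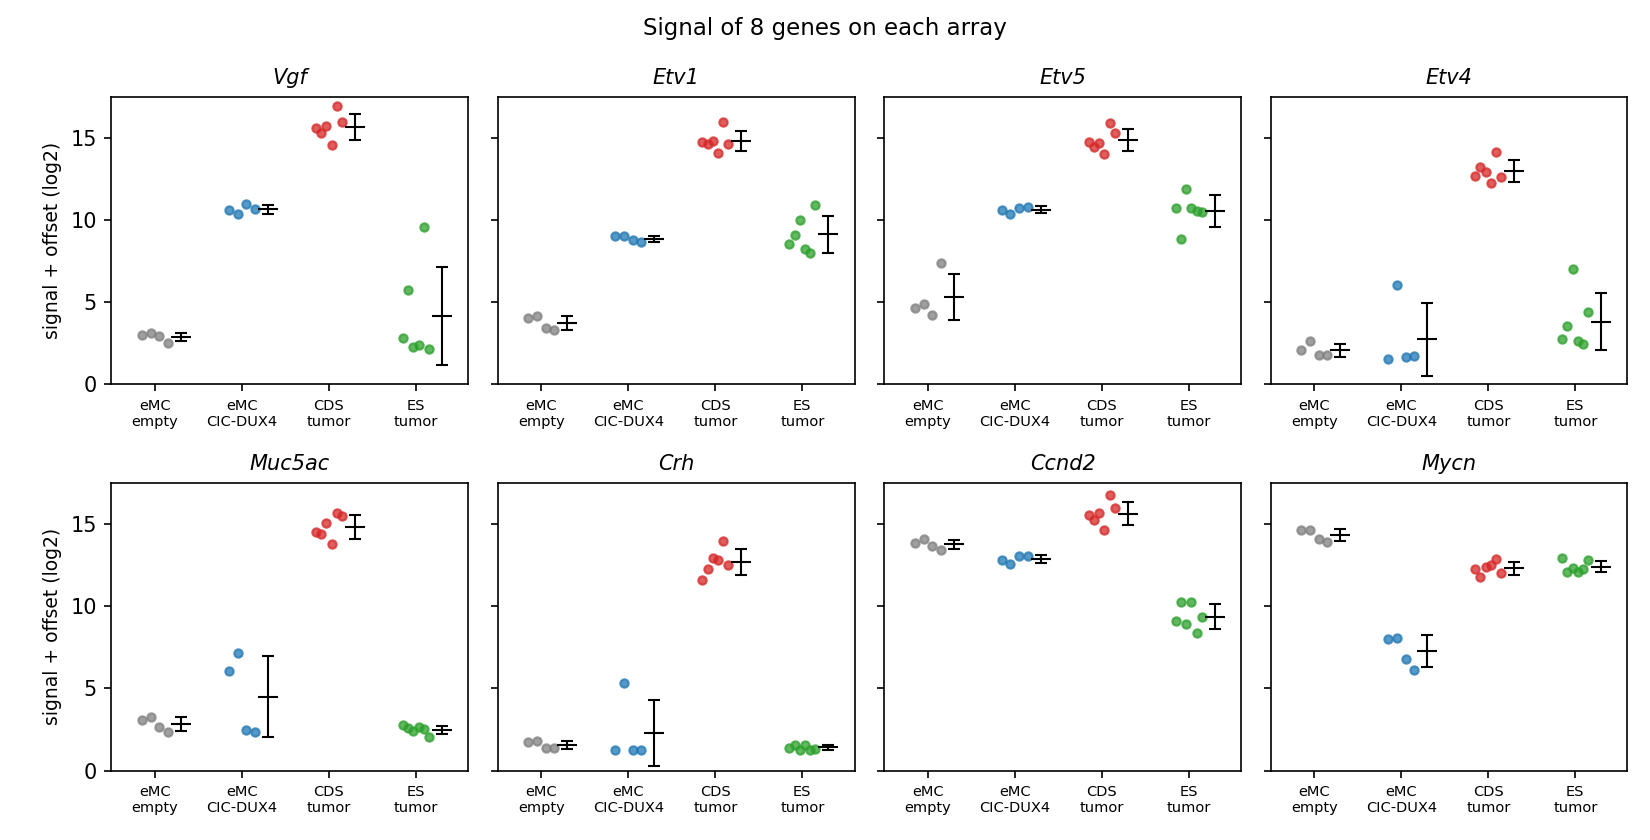
Log2 signal of 8 genes on each array of the 4 groups, with mean ± SD beside the points. Vgf was 10.64 ± 0.27 in eMC CIC-DUX4 and 2.89 ± 0.25 in eMC empty, while the plotted Mycn probe set was 7.25 ± 0.97 and 14.31 ± 0.35.

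The comparison of CDS tumors with eMC empty asked how the tumors differ from the mesenchymal cells without the fusion. Spx, which encodes the secreted peptide spexin, was at least 508-fold higher in CDS tumors, with a mean log2 signal of 15.84 ± 0.83 (SD, n = 6) against 2.36 ± 0.44 (n = 4). Its log2 fold change was 13.48 ± 0.50 (SE, quantile 13.04 ± 0.16). Vgf was at least 450.0-fold higher (12.77 ± 0.48, quantile 12.03), and Muc5ac, a secreted gel-forming mucin, at least 251-fold (11.99 ± 0.51, quantile 11.42 ± 0.20). Etv1 was at least 248-fold higher (11.07 ± 0.47, quantile 9.15) and Etv4 at least 70.1-fold (10.90 ± 0.65, quantile 10.78 ± 0.28). Crh, corticotropin-releasing hormone, was at least 56.5-fold higher (11.10 ± 0.71, quantile 10.98). Among the genes that fell, Cidea, a lipid droplet protein, was at least 132-fold lower (-10.17 ± 0.88, quantile -9.77) and Ucp1, the uncoupling protein of brown fat, at least 49.8-fold (-8.68 ± 0.91, quantile -8.72). Twist2, a transcription factor of mesenchymal cells, was at least 42.6-fold lower (-8.68 ± 0.92, quantile -8.77).

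The other genes with the highest fold changes were Rgs5, a pericyte regulator of G protein signalling (at least 249-fold, 11.94 ± 0.50, quantile 11.32), Aldoc (at least 178-fold, 11.18 ± 0.51, quantile 10.34) and the importin Kpna7 (at least 105-fold, 11.14 ± 0.59, quantile 10.93). Among the genes of the lowest values, Thrsp, a lipogenic regulator, changed by -9.12 ± 1.46 and Saa3 by -8.03 ± 1.07. The basal keratin Krt14 was at least 19.2-fold lower (-7.82 ± 0.88), and tissue factor F3 changed by -7.69 ± 1.05 and Gpnmb by -7.62 ± 0.90. Quantile values ran from -8.65 for Thrsp to -6.86 for Gpnmb. Adjusted p (limma, Benjamini-Hochberg) was 1.59e-11 for Spx, 9.62e-09 for Crh and 0.000314 for Thrsp.

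Etv5 rose by 9.55 ± 0.56 (quantile 7.13) and Fli1, an ETS factor, was at least 71.9-fold higher (9.10 ± 0.55, quantile 7.00). The D-type cyclins Ccnd1 and Ccnd2 rose by 2.06 ± 0.31 and 1.88 ± 0.29 (quantile 2.23 and 2.09). Cic was higher by 3.53 ± 1.03 (adjusted p = 0.0225, quantile 1.24 ± 0.34). Its adjusted p was 0.0519 without CDS tumor 4 and 0.0737, 0.0624 and 0.0680 without eMC empty 4, 5 and 6. Erg (2.39 ± 0.84, adjusted p = 0.0504) and Ewsr1 (0.50 ± 0.33) were not called, but Erg was after quantile normalization (1.73).

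In all, 2518 genes were called, 1801 higher and 717 lower (71.5% higher), and 4533 after quantile normalization, 2164 higher and 2369 lower (47.7% higher). On both scales, 2109 were called in the same direction. With each array scaled to the same median 1054 were called, 551 higher and 503 lower (52.3% higher), and 9 of the 51 genes named here lost their call, among them Ccnd1, Ccnd2 and Cic (adjusted p = 0.209, 0.267 and 0.189). The count was 1490 without eMC empty 4 and 1586 without eMC empty 5.

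Of the 22 lists 9 were called as deposited and 8 after quantile normalization, 8 of them on both scales. CIC target genes had the smallest adjusted p of them. Of 18, 16 were called higher and 0 lower, 16 adjusted over the list alone and 16 after quantile normalization. The CIC target list had an adjusted p of 5.64e-16 (adjusted p = 0.0163 with an estimated correlation). Stress response genes were lower as a group, with 3 of 11 called lower (5 adjusted over the list alone), among them Asns, which makes asparagine (-4.44 ± 0.60, quantile -3.77). The stress list had an adjusted p of 2.69e-06, and adjusted p = 0.0163 with an estimated correlation (0.120 when quantile normalized too). Collagen and extracellular matrix genes were lower as well, with 0 of 20 called higher and 5 lower (6 adjusted over the list alone). The collagen list had an adjusted p of 2.70e-08 (adjusted p = 0.179 with an estimated correlation), and was not called after quantile normalization (0.230). The proteoglycans Dcn and Lum changed by -3.11 ± 0.60 and -2.20 ± 0.50 (quantile -2.35 and -1.67) and the collagen cross-linking enzyme Lox by -2.04 ± 0.30 (quantile -1.39). Interferon response genes were lower, with 4 of 11 called lower (5 adjusted over the list alone). The interferon list had an adjusted p of 5.47e-05 (adjusted p = 0.291 with an estimated correlation, and 0.0146 when quantile normalized too). Usp18, a negative regulator of interferon signalling, changed by -5.30 ± 1.01 (quantile -4.65) and Ifit1 by -3.41 ± 0.71 (quantile -3.39).

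Markers of cells that a tumor takes from its host moved with the group, and so did the 3′ excess of Actb (0.80 log2 in CDS tumors, 0.17 in eMC empty, exact permutation p = 0.0190, adjusted 0.0508). Some of these markers also moved in culture, without a host. In eMC CIC-DUX4 against eMC empty, 3 of 14 endothelial and 2 of 6 pericyte genes were called higher on both scales and 0 lower. Plvap and Rgs5 were among them (quantile 2.19 and 1.52). Endothelial genes were higher, 11 of 14 (13 adjusted over the list alone). The endothelial list had an adjusted p of 1.03e-08 (adjusted p = 0.0596 with an estimated correlation, and 0.00507 when quantile normalized too). Plvap, a protein of vessel fenestrae, was at least 75.9-fold higher (10.23 ± 0.57, quantile 9.79) and Cdh5, vascular cadherin, at least 37.5-fold (9.32 ± 0.65, quantile 9.01). Pericyte genes were higher, 4 of 6 (5 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.0596 with an estimated correlation). Macrophage genes were higher too, 8 of 15 (10 adjusted over the list alone), with the complement gene C1qa at least 36.2-fold higher (7.35 ± 0.63, quantile 4.71). The macrophage list had an adjusted p of 0.00230 (adjusted p = 0.401 with an estimated correlation). The globin Hba-a1, a red cell gene, was at least 144-fold higher (9.75 ± 0.55, quantile 7.43), but its erythroid list had 2 measured members and was not tested. Adipocyte genes were lower, 5 of 7 (5 adjusted over the list alone), led by Pparg, the master regulator of fat cells (-7.16 ± 1.08, quantile -7.57). The adipocyte list had an adjusted p of 1.12e-05 (adjusted p = 0.0676 with an estimated correlation). Keratinocyte genes were lower, 2 of 9 (2 adjusted over the list alone, adjusted p = 0.000129). With an estimated correlation adjusted p was 0.0839 (0.0146 when quantile normalized too). Neutrophil (3 of 7 higher, adjusted p = 0.127), lymphocyte (0 of 4, 0.861) and skeletal muscle markers (1 of 14, 0.319) were not called. Each of these lists had as many called adjusted over the list alone.

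Hypoxia and glycolysis genes were not called as a list, with 8 of 19 higher and 2 lower (10 adjusted over the list alone, adjusted p = 0.288). The carbonic anhydrase Car9 was at least 29.9-fold higher (8.79 ± 0.71, quantile 8.26) and Vegfa rose by 6.06 ± 0.73 (quantile 4.08), while the vasodilator peptide Adm changed by -6.40 ± 1.14 (quantile -5.17). Neither were cartilage genes, with 5 higher and 1 lower of 15 (9 adjusted over the list alone, adjusted p = 0.127). Comp, a cartilage matrix protein, was at least 12.4-fold higher (6.51 ± 0.81, quantile 4.43) and Col9a1, type IX collagen, was higher by 5.86 ± 0.64 (quantile 4.59). Of MAPK immediate-early genes 5 of 13 were higher and 1 lower (7 adjusted over the list alone, adjusted p = 0.319). Fos rose by 4.74 ± 0.65 (quantile 3.34) and the MAPK phosphatase Dusp1 by 4.58 ± 0.58 (quantile 3.46), while Egr1 changed by -3.70 ± 0.90 (quantile -3.00). Other lists had calls both ways and were not called. These were the Ewing sarcoma list (4 higher and 4 lower of 19, 9 adjusted over the list alone, adjusted p = 0.151) and the cell cycle list (1 and 1 of 29, 2 adjusted over the list alone, adjusted p = 0.0612). Smooth muscle had 2 higher and 3 lower of 12, neural genes 1 and 2 of 12 and Wnt genes 1 and 2 of 9. Adjusted over the list alone, 7, 4 and 3 were called, and the lists had adjusted p of 0.151, 0.231 and 0.195. Bone had 1 of 5 higher (adjusted p = 0.802) and p53 targets 0 of 12 (0.893), with as many adjusted over the list alone. The Ewing sarcoma, cell cycle, smooth muscle and lymphocyte lists tested below the other genes with positive medians and means, and the neural and Wnt lists with negative medians and positive means.

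The comparison of CDS with ES tumors asked what sets CIC-DUX4 tumors apart from other tumors. Spx was at least 1843-fold higher in CDS tumors, with a mean log2 signal of 15.84 ± 0.83 (SD, n = 6) against 2.45 ± 0.12 (n = 6). Its log2 fold change was 13.39 ± 0.48 (SE, quantile 12.40 ± 0.18) with an adjusted p of 7.02e-12. Cytl1, a cytokine-like protein of cartilage, was at least 1283-fold higher (12.83 ± 0.50, quantile 11.86) and Muc5ac at least 911-fold (12.34 ± 0.52, quantile 11.47). Col9a1 was higher by 11.57 ± 0.78 (quantile 11.32) and Vgf by 11.50 ± 1.01. Signals of Col9a1 were 2.10 to 2.30, below the dip, in the ES tumors other than tumor 51 (6.98), so its fold change is not exact. Crh was at least 205-fold higher (11.26 ± 0.75, quantile 10.95). In ES tumors the adhesion protein gene Mpzl2 was at least 159-fold higher than in CDS tumors (-11.24 ± 0.71, quantile -11.42) and the forkhead factor gene Foxd4 at least 131-fold (-10.70 ± 0.71, quantile -10.89). The epithelial keratin Krt20 was at least 103-fold higher there (-10.09 ± 0.76, quantile -10.15) and the desmosomal cadherin Dsg2 at least 71.4-fold (-9.61 ± 0.82, quantile -9.52).

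Kpna7 (at least 382-fold, 11.29 ± 0.62, quantile 10.66) and Aldoc (10.98 ± 0.63, quantile 10.21) completed the highest fold changes. Zfp804a (at least 60.9-fold, -9.82 ± 0.83), Tmprss11a (at least 37.8-fold, -9.44 ± 0.91), the axon guidance gene Sema3e (at least 81.6-fold, -9.36 ± 0.71) and the fucosyltransferase Fut9 (at least 53.02-fold, -9.31 ± 0.82) completed the lowest, with quantile values of -9.79, -9.21, -9.40 and -9.21. All 3 PEA3 factors were higher in CDS tumors: Etv4 by 9.18 ± 0.76 (quantile 8.78), Etv1 by 5.68 ± 0.44 (quantile 6.17) and Etv5 by 4.30 ± 0.40 (quantile 4.46). Ccnd2 rose by 6.26 ± 0.36 (quantile 6.80), Ccnd1 by 2.14 ± 0.29 (quantile 1.66) and Fli1 by 3.60 ± 0.37 (quantile 4.36). Cic (1.63 ± 0.96, adjusted p = 0.219), Erg (1.36 ± 0.92) and Ewsr1 (0.20 ± 0.26) were not called, but Cic was after quantile normalization (2.20 ± 0.42). ES tumor 48 had Cic at 3.54, against 7.44 to 8.74 in the other ES tumors, and so adds to its change. Nkx2-2 had 1 probe set, too dim to be tested.

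In all, 2564 genes were called, 1382 higher in CDS and 1182 higher in ES tumors (53.9% higher in CDS), and 4083 after quantile normalization, 2090 and 1993 (51.2%). On both scales, 2322 were called in the same direction. With each array scaled to the same median the balance turned: 3161 were called, 507 higher in CDS and 2654 higher in ES tumors (16.0% higher in CDS), and 9 of the 47 genes named here lost their call, among them Ccnd1, Col5a1, Ccn2, Ccn1 and Eng (adjusted p = 0.193, 0.0765, 0.0744, 0.141 and 0.0574).

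Of the 22 lists 7 were called as deposited and 7 after quantile normalization, 6 of them on both scales. CIC target genes were higher in CDS tumors, 17 of 18 against 1 lower (18 adjusted over the list alone). The CIC target list had an adjusted p of 1.25e-16 (adjusted p = 0.00303 with an estimated correlation). The member that was lower was the cyclin gene Ccne1 (-3.59 ± 0.87, quantile -2.44). Cartilage genes were higher, 10 of 15 and 0 lower (11 adjusted over the list alone). The cartilage list had an adjusted p of 3.83e-08, and adjusted p = 0.00303 with an estimated correlation (0.0509 when quantile normalized too). Col2a1, type II collagen, was at least 281-fold higher (10.97 ± 0.64, quantile 10.46), Col9a3 higher by 7.58 ± 1.04 (quantile 7.02) and Comp by 7.23 ± 1.06 (quantile 6.89). Collagen and extracellular matrix genes were higher, 13 of 20 (14 adjusted over the list alone), among them Loxl1 (3.99 ± 0.44, quantile 4.74), Col1a1 (3.62 ± 0.49, quantile 4.45) and Col5a1 (2.72 ± 0.38, quantile 3.20). The collagen list had an adjusted p of 3.63e-08 (adjusted p = 0.428 with an estimated correlation). Smooth muscle and myofibroblast genes were higher, 4 of 12 (5 adjusted over the list alone), with the matricellular genes Ccn2 and Ccn1 up by 2.63 ± 0.36 and 2.49 ± 0.46 (quantile 2.43 and 3.16). The smooth muscle list had an adjusted p of 0.00625 (adjusted p = 0.428 with an estimated correlation). In the same arrays the 3′ excess of Actb was 0.80 log2 in CDS and 0.25 in ES tumors.

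Hypoxia and glycolysis genes were higher, 7 of 19 against 2 lower (10 adjusted over the list alone, adjusted p = 0.0166, and adjusted p = 0.428 with an estimated correlation). The hypoxia list was not called after quantile normalization (0.0994) or without CDS tumor 5 (0.0813). Car9 was at least 108-fold higher (9.10 ± 0.73, quantile 8.27), whereas Pfkp, a phosphofructokinase, changed by -5.45 ± 0.59 (quantile -5.35). Cell cycle and DNA replication genes were lower, with 0 higher and 6 lower of 29 (6 adjusted over the list alone). The cell cycle list had an adjusted p of 0.00400 (adjusted p = 0.575 with an estimated correlation). The mitotic kinases Aurka (-2.70 ± 0.69, quantile -2.52) and Bub1 (-2.12 ± 0.57, quantile -1.91) were among them. The mean of this list was 8.87 in CDS tumor 5 and 10.23 to 10.84 in the other CDS tumors. Endothelial markers were higher, 5 of 14 (6 adjusted over the list alone), for instance Plvap (3.39 ± 0.29, quantile 4.06), Cdh5 (3.38 ± 0.46, quantile 4.28) and Eng (3.56 ± 0.70, quantile 3.98). The endothelial list had an adjusted p of 0.00198 (adjusted p = 0.428 with an estimated correlation).

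The other markers of host cells were not called as lists. Pericytes had 2 of 6 higher (adjusted p = 0.284), with Rgs5 higher by 2.19 ± 0.34. Macrophages had 0 of 15 called (0.0682), with Lyz2 at 0.01 ± 0.61, and lymphocytes 1 of 4 higher (0.354). Neutrophils had 1 higher and 1 lower of 7 (0.664) and skeletal muscle 0 of 14 (0.284). Each of these lists had as many called adjusted over the list alone. The muscle list had means of 14.93, 13.69 and 13.40 in CDS tumors 3, 4 and 5, of 4.09, 5.86 and 4.80 in CDS tumors 1, 2 and 6, and of 2.91 (tumor 51) to 14.71 (tumor 48) in ES tumors. Keratinocytes had 2 of 9 lower (3 adjusted over the list alone, adjusted p = 0.0826), with Krt10 at -4.52 ± 1.00, and adipocytes 0 of 7 (0 adjusted over the list alone, adjusted p = 0.711). The keratinocyte list had a mean of 10.39 in ES tumor 48 and of 3.14 to 4.76 in the other ES tumors. The adipocyte list tested above the other genes with a negative median and mean.

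MAPK immediate-early genes had 5 of 13 higher and 2 lower (7 adjusted over the list alone, adjusted p = 0.128). Fosl1, a Fos family factor, was at least 6.60-fold higher (5.14 ± 0.83, quantile 4.27) and Dusp1 rose by 3.35 ± 0.43, while Egr1 changed by -3.15 ± 0.79 (quantile -2.72). Neural genes had 4 of 12 higher and 1 lower (6 adjusted over the list alone, adjusted p = 0.399), with the adhesion molecule Ncam1 higher by 6.65 ± 1.04 (quantile 6.08). Wnt genes had 3 of 9 higher (3 adjusted over the list alone, adjusted p = 0.218), with Dkk3 at least 29.9-fold higher (7.03 ± 0.93, quantile 6.40). Interferon response genes had 2 of 11 higher (2 adjusted over the list alone, adjusted p = 0.0965). After quantile normalization the interferon list was called (0.0185, but adjusted p = 0.721 with an estimated correlation), and its mean log2 signal as deposited was 8.79 in ES tumor 47 against 3.17 to 4.66 in the other ES tumors. For p53 targets 3 of 12 were higher (3 adjusted over the list alone, adjusted p = 0.354), with a negative median (-0.12), a positive mean (0.38) and a test above the other genes. Stress response genes had 3 of 11 lower (4 adjusted over the list alone, adjusted p = 0.163), among them Asns (-3.71 ± 0.51, quantile -3.70). Ewing sarcoma genes had 3 higher and 3 lower of 19 (9 adjusted over the list alone, adjusted p = 0.331). Bone genes had 1 and 1 of 5 (2 adjusted over the list alone, adjusted p = 0.664), the bone sialoprotein Ibsp at least 4.27-fold higher (5.81 ± 1.13, quantile 6.07) and the transcription factor Dlx5 lower (-5.97 ± 0.93, quantile -5.55).

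The comparison of CDS tumors with eMC CIC-DUX4 asked what differs between cells 48 hours after transduction and the tumors with the same fusion. Spx was higher in CDS tumors by 11.48 ± 0.81 (SE, n = 6 against 4), 12.41 above all genes and 12.19 ± 0.13 after quantile normalization. Etv4 was higher by 10.24 ± 0.84 (quantile 10.63) and Crh by 10.38 ± 0.84 (quantile 10.90). Both were below the dip in the other 3 eMC CIC-DUX4 arrays, but eMC CIC-DUX4 6 had no dip and higher signals (6.06 and 5.30), so no bound is given. Muc5ac rose by 10.32 ± 0.84 (quantile 11.20) and Kpna7 by 10.11 ± 0.71 (quantile 10.74). Cidea was at least 89.7-fold lower (-9.62 ± 0.75, quantile -9.88) and Ucp1 at least 76.8-fold (-9.31 ± 0.75, quantile -9.67). Cck, a gut and brain peptide, was at least 36.6-fold lower (-9.14 ± 0.78, quantile -9.24), Stmn2, a neuronal microtubule regulator, at least 44.0-fold (-8.70 ± 0.77, quantile -8.70) and Krt14 at least 28.6-fold (-8.40 ± 0.78, quantile -8.20).

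Adjusted p (limma) was 3.68e-06 for Etv4 and at most 1.01e-05 for the other 9 genes of this kind. Etv1 rose by 5.95 ± 0.31 (quantile 7.15), Etv5 by 4.22 ± 0.30 (quantile 4.26), Vgf by 5.02 ± 0.34 (quantile 4.93), Fli1 by 5.26 ± 0.42 (quantile 7.16), Ccnd1 by 2.69 ± 0.31 (quantile 2.01) and Ccnd2 by 2.77 ± 0.30 (quantile 2.06). Cic (-0.31 ± 0.79) and Erg (1.69 ± 1.22) were not called, but Erg was after quantile normalization (1.66). Ewsr1 was called at 1.10 ± 0.32 (adjusted p = 0.0298) but not after quantile normalization (0.70). Leaving out CDS tumor 1, 3 or 6 gave Ewsr1 an adjusted p of 0.0562, 0.0524 or 0.0515, and eMC CIC-DUX4 5, 6 or 7 of 0.0874, 0.0921 or 0.0571; without CDS tumor 5 its change was 0.85.

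In all, 2202 genes were called, 634 higher and 1568 lower (28.8% higher), and 4575 after quantile normalization, 2078 higher and 2497 lower (45.4% higher). On both scales, 2041 were called in the same direction. With each array scaled to the same median 1055 were called, 442 higher and 613 lower (41.9% higher), and 9 of the 43 genes named here lost their call, among them Ccnd1, Ccnd2, Ewsr1, Usp18, Egln3 and Cd14 (adjusted p = 0.105, 0.0929, 0.584, 0.222, 0.0584 and 0.229). The count was 898 without the 3 arrays of high median, 3377 without CDS tumor 2, and 1097, 1217 and 1258 without eMC CIC-DUX4 5, 6 and 7.

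Of the 22 lists 8 were called as deposited and 8 after quantile normalization, 6 of them on both scales. CIC target genes were higher in the tumors, 13 of 18 and 0 lower (14 adjusted over the list alone). The CIC target list had an adjusted p of 1.16e-24 (adjusted p = 0.0189 with an estimated correlation). Hypoxia and glycolysis genes were higher too, 8 of 19 against 1 lower (11 adjusted over the list alone, adjusted p = 3.45e-09, and adjusted p = 0.0205 with an estimated correlation, 0.482 when quantile normalized too). Car9 rose by 7.13 ± 0.93 (quantile 8.13) and Egln3, an oxygen-sensing hydroxylase, by 3.36 ± 0.41 (quantile 5.07), while Adm changed by -6.64 ± 1.16 (quantile -6.05). Endothelial markers were higher, 7 of 14 (8 adjusted over the list alone), Cdh5 by 7.72 ± 0.87 (quantile 8.82) and Plvap by 5.51 ± 0.34 (quantile 7.60). The endothelial list had an adjusted p of 1.32e-09 (adjusted p = 0.168 with an estimated correlation, and 0.0177 when quantile normalized too). Macrophage markers were higher, 5 of 15 against 1 lower (8 adjusted over the list alone), C1qa by 7.29 ± 0.94 (quantile 8.35), with Cd14 lower (-4.25 ± 0.97, quantile -3.65). The macrophage list had an adjusted p of 0.00145 (adjusted p = 0.452 with an estimated correlation, and 0.510 with the replicate number as a block). Skeletal muscle markers were called higher as a list with 1 of 14 members called (0 adjusted over the list alone, adjusted p = 0.00145, and adjusted p = 0.515 with an estimated correlation). The list's mean log2 signal was 13.40 to 14.93 in CDS tumors 3, 4 and 5, 4.09 to 5.86 in CDS tumors 1, 2 and 6, and 5.68 to 8.15 in eMC CIC-DUX4. The muscle list was not called after quantile normalization (0.129) or without CDS tumor 5 (0.0690). In the same arrays the 3′ excess of Actb was 0.80 log2 in CDS tumors and 0.22 in eMC CIC-DUX4 (exact permutation p = 0.0190, adjusted 0.0508).

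Keratinocyte markers were lower, 5 of 9 (7 adjusted over the list alone, adjusted p = 0.000154). With an estimated correlation adjusted p was 0.168 (0.0182 when quantile normalized too). Dsp, a desmosomal protein, was at least 12.6-fold lower (-7.32 ± 0.76, quantile -6.28) and Trp63, the transcription factor of basal epithelium, at least 2.13-fold (-4.68 ± 0.73, quantile -2.55). Interferon response genes were lower, 6 of 11 (7 adjusted over the list alone), with Usp18 at -4.24 ± 1.02 (quantile -2.98). The interferon list had an adjusted p of 0.0148 (adjusted p = 0.515 with an estimated correlation). Wnt pathway targets and antagonists were lower, 5 of 9 (5 adjusted over the list alone), with Dkk2 at least 25.6-fold lower (-8.14 ± 0.77, quantile -7.67). The Wnt list had an adjusted p of 0.0438 (adjusted p = 0.317 with an estimated correlation). Its call was lost after quantile normalization (0.0960), without the 3 arrays of high median (0.0704) and without CDS tumor 2, 4 or 5 (0.0674, 0.0660 and 0.151).

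Adipocyte genes were not called as a list (0 higher and 4 lower of 7, adjusted p = 0.0511), with Pparg at -7.63 ± 1.00 (quantile -8.14). Stress response genes were not called either (0 and 5 of 11, 0.585), with Asns at -3.28 ± 0.62 (quantile -3.47). The Ewing sarcoma list (1 and 7 of 19, 0.186) and the neural list (1 and 4 of 12, 0.287) held the stem cell factor Sox2. Sox2 was at least 10.1-fold lower (-6.64 ± 0.78, quantile -5.07). Cartilage genes had 2 higher and 4 lower of 15 (0.656), with Hapln1 at least 12.9-fold lower (-6.66 ± 0.78, quantile -5.42). Each of these lists had as many called adjusted over the list alone. The next 6 lists were tested above the other genes despite a negative mean, and none was called. Cell cycle genes had 2 higher of 29 (adjusted p = 0.0587) and smooth muscle 3 of 12 (0.0828). MAPK genes had 2 and 2 of 13 (0.197), bone 1 and 1 of 5 (0.785) and p53 targets 1 and 1 of 12 (0.656). Adjusted over the list alone these had 1, 3, 4, 2 and 1 called. Collagen genes had 2 higher and 3 lower of 20 (6 adjusted over the list alone, adjusted p = 0.192), and lay below the other genes after quantile normalization (0.0419, but adjusted p = 0.589 with an estimated correlation). Pericytes (1 higher of 6, adjusted p = 0.0828), lymphocytes (1 lower of 4, 0.312) and neutrophils (1 higher of 7, 0.0615) were not called. Each list had 1 called adjusted over the list alone.

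**Figure D3:**
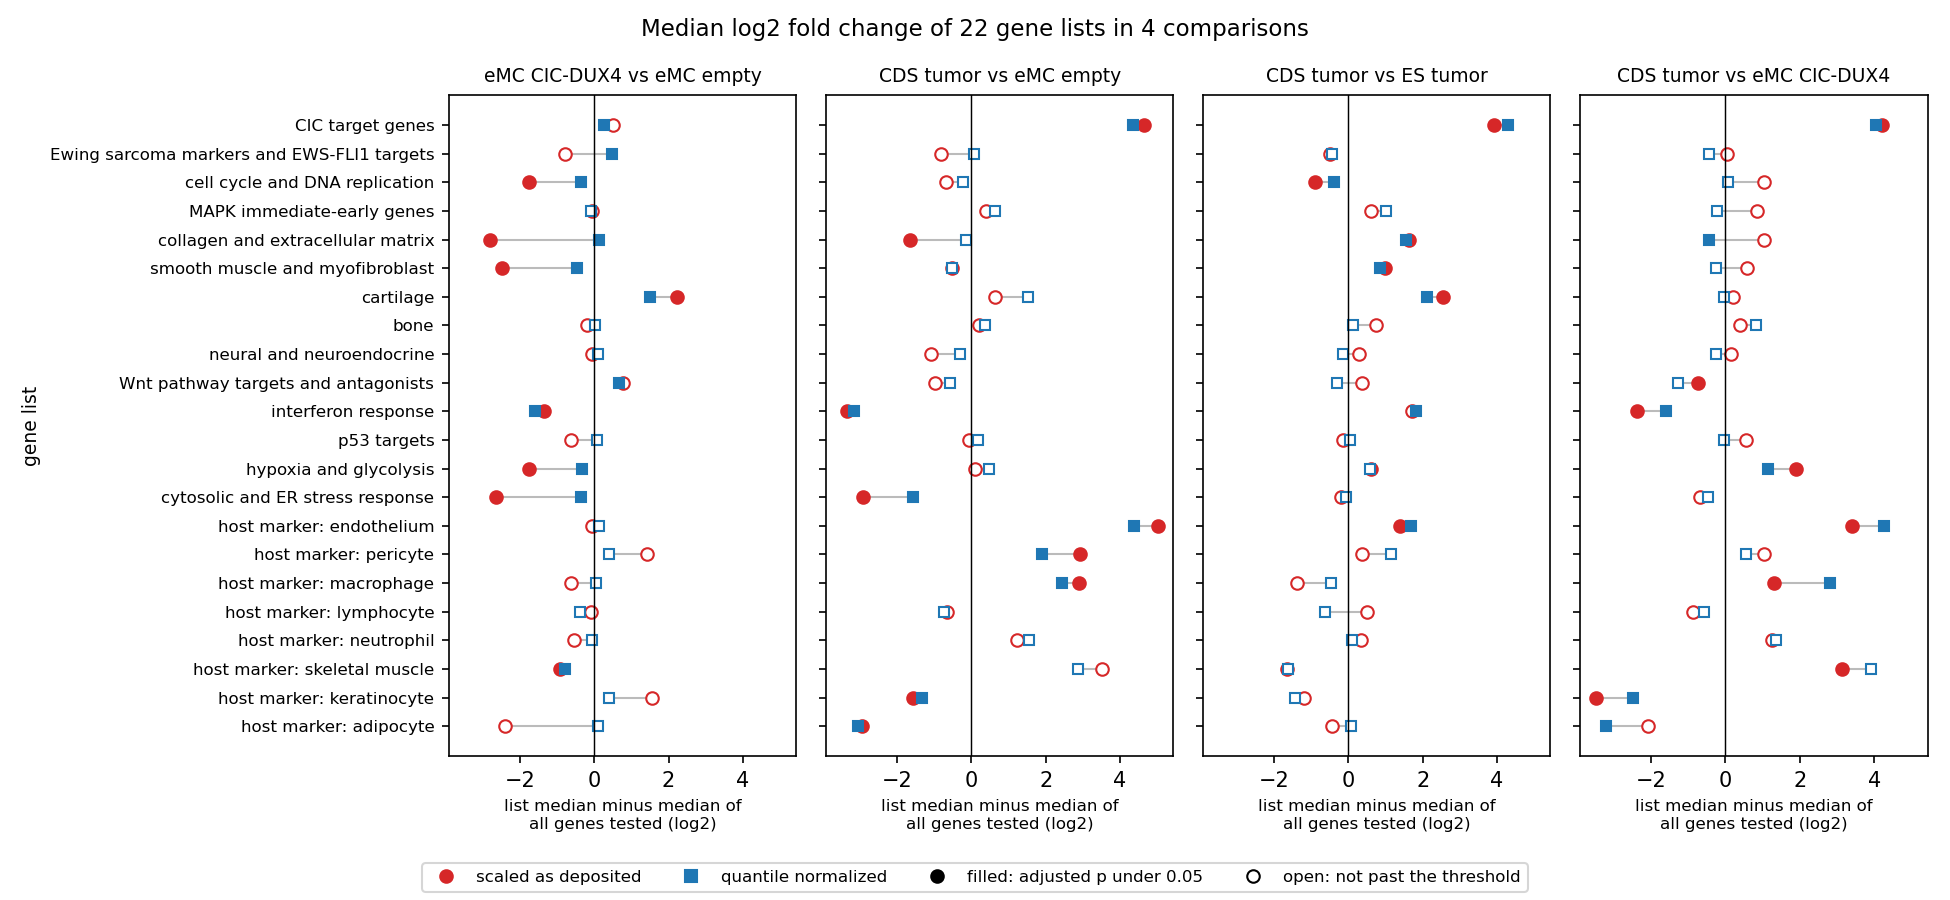
For each comparison and each of the 22 gene lists tested, the median log2 fold change of the list minus that of all genes tested, as deposited (red circles) and after quantile normalization (blue squares), filled where the list's adjusted p was under 0.05. CIC target genes are filled on both scales in the 3 comparisons of CDS tumors.

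The overlap of calls asked whether the genes that changed in cultured cells were those that set CDS apart from ES tumors, 2 comparisons without a shared array. After quantile normalization, 270 genes were higher in both eMC CIC-DUX4 (against eMC empty) and CDS tumors (against ES tumors), where 169 would share by chance (Fisher's exact test, two-sided, adjusted p = 3.44e-16), and 140 were lower in both against 95.9 by chance (adjusted p = 5.78e-06). As deposited, 566 were higher in both against 642 by chance (adjusted p = 2.70e-05), on the other side of chance, and 29 were lower in both against 54.6 (adjusted p = 0.000123). With no filter on dim probe sets the deposited values gave 482 higher in both against 405 by chance (Fisher's exact test, two-sided, p = 2.10e-06), so the side of chance of the genes higher in both depended on the filter. Those lower in both were 29 against 35.3 (Fisher's exact test, p = 0.289). On both scales 93 genes were called higher in these comparisons and in CDS tumors against eMC empty, which shares arrays with both. They held Vgf, Etv1, Etv5, Bmp2, Aldoc, Vegfa, Col9a1, Col2a1 and the integrin gene Itga8. The last was at least 7.34-fold, 57.1-fold and 207-fold higher (quantile 3.48, 7.28 and 9.33) in eMC CIC-DUX4 against eMC empty, CDS tumors against eMC empty and CDS against ES tumors.

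Of the genes called in eMC CIC-DUX4 and in CDS tumors against the same eMC empty arrays, 1379 were called in the same direction (1189 higher, 190 lower). Independent lists of these sizes would share 870. Simulated groups held no changed gene and shared 0 calls, which is no comparison for this count. With the 4 controls split between the comparisons the mean count was 689 (519 to 1032 over 6 splits). Across genes, which are not independent replicates, the fold changes of both comparisons had a covariance of 1.74 (0.258 simulated), a correlation of 0.524 and the same sign in 83.1% of genes. This simulation left out the differences between the arrays' distributions. With these alone, unchanged groups had median changes of 2.11 and 1.13 in the 2 comparisons, so as deposited 0.258 is not the value of unchanged groups, and part of the agreement may come from the distributions. After quantile normalization 590 were shared (331 higher, 259 lower), against 289 for independent lists and 485 (460 to 509) with split controls. On that scale the covariance was above the simulated value (0.249 against 0.0231). The correlation (0.201 against 0.359) and the share of genes with the same sign (58.6% against 62.9%) were below the simulated values. This cannot decide agreement, because unchanged groups share only the noise of the common controls. With split controls correlation and share averaged 0.178 and 57.0%.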

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

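The rule used here, that the highest or lowest array of a group lies farther from the others than Dixon's 95% limit, was set before the data were examined, and no test in this part was chosen after its result was seen. The rule marked 34 of 311 values; chance marks about 1 in 20 groups. Values are log2 signals, and for lists the mean over the members.

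In eMC CIC-DUX4, replicate 6, the array with no dip, was marked for 9 values. It lay above the other 3 arrays for Etv4 (6.06 against 1.56 to 1.69), Erg (6.71 against 1.73 to 2.05), Crh (5.30 against 1.28), Foxd4 (5.44), Krt20 (5.75), Zfp804a (5.02), Tmprss11a (4.02) and Fut9 (5.74), and below them for the cell cycle and DNA replication list (10.53 against 10.64 to 10.65).

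In ES tumors, tumor 47 had Erg at 6.62 (others 2.28 to 3.32), Bmp2 at 5.63 (2.16 to 3.26), Hp at 2.26 (8.90 to 12.36), Dsg2 at 9.45 (11.79 to 13.04), the neural and neuroendocrine list at 4.16 (3.12 to 3.50) and the interferon response list at 8.79 (3.17 to 4.66). Tumor 51 had Cxcl1 at 5.47 (2.63 to 3.58), Mylpf at 2.47 (11.68 to 15.16), Aldoc at 5.86 (2.45 to 3.44), Thrsp at 10.07 (2.29 to 3.52) and Col9a1 at 6.98 (2.10 to 2.30). Tumor 48 had Cic at 3.54 (7.44 to 8.74), Krt14 at 11.05 (1.68 to 1.99), F3 at 4.09 (7.37 to 8.91) and the keratinocyte list at 10.39 (3.14 to 4.76). Tumor 41 had Ucp1 at 3.17 (1.80 to 2.28) and Cytl1 at 3.23 (2.17 to 2.55).

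In CDS tumors, tumor 2 had Thrsp at 11.58 (others 2.39 to 3.05) and the bone list at 6.36 (3.14 to 4.32), tumor 5 the cell cycle and DNA replication list at 8.87 (10.23 to 10.84), and tumor 6 the smooth muscle and myofibroblast list at 8.79 (10.28 to 11.04). In eMC empty, replicate 7 had the CIC target list at 6.99 (6.03 to 6.16), the neural list at 4.50 (3.69 to 3.75), the pericyte list at 5.47 (3.92 to 4.17) and the macrophage list at 7.22 (6.20 to 6.34).

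Of 7355 probe sets with no or several gene symbols, which the gene counts leave out, 2890 were called in eMC CIC-DUX4 against eMC empty, 1307 in CDS tumors against eMC empty, 1400 in CDS against ES tumors and 934 in CDS tumors against eMC CIC-DUX4. After quantile normalization these counts were 868, 2612, 1954 and 2365.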

How the results depend on the processing

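The settings without the 3 arrays of high median (CDS tumor 2, eMC CIC-DUX4 5 and 6), those that pair quantile normalization with another setting, and those applied to the quantile-normalized count were chosen after seeing the data; all others were fixed before, and all were run. After quantile normalization the counts of genes were 1590, 4533, 4083 and 4575 for eMC CIC-DUX4 against eMC empty and CDS tumors against eMC empty, ES tumors and eMC CIC-DUX4; without the 3 arrays as well, they were 1623, 4512 and 3591 for the comparisons with eMC arrays. Scaling each array to the same median gave 20, 1054 and 1055 for these, and 3161 for CDS against ES tumors, with 16.0% higher where 53.9% were as deposited; the cause was not tested. Array weights per group gave 3603 and leaving out the 3 arrays 898 in CDS tumors against eMC CIC-DUX4; the cause was not tested. The lists called were 0, 2, 2 and 2 with an estimated correlation, 3, 4, 1 and 3 with quantile normalization too, 18 with fry in eMC CIC-DUX4 against eMC empty (8 with camera), 5 there without the 3 arrays, and 13 with no filter in CDS tumors against eMC CIC-DUX4; the cause was not tested. The list of CIC target genes was called under every setting run in the 3 comparisons of CDS tumors (22, 23 and 22 settings). Of the 57 genes counted as named in eMC CIC-DUX4 against eMC empty, 15 that were called on either scale turned their sign after quantile normalization. Changes of sign of genes called on neither scale, such as Ccnd1, Ccnd2 and Ewsr1, are not among the 15. The 57 were counted by the rule given above. The 15 were Actg2 (-1.13), Ccne1 (-1.13), Cdc45 (-0.92), Ckm (-0.35), Col3a1 (0.038), Des (-0.019), E2f1 (-0.28), Egln3 (-1.52), Fli1 (-0.16), Loxl2 (-0.65), Mx2 (-1.62), Ndrg1 (-0.23), Rsad2 (-1.25), Tnni2 (-1.75) and Tnnt3 (-1.45). A further 11 were weaker. Of the 57, 49 lost their call with median scaling, and 18 with all groups in the same fit. Without each array in turn, the counts of genes ran from 5286 to 6938, 1490 to 3327, 1818 to 2833 and 1097 to 3377 in the order above, and from 1586 to 1660 in the first after quantile normalization; the lists ran from 5 to 8, 9 to 10, 6 to 10 and 7 to 10. The lowest list count was without eMC empty 7, and the lowest gene counts in the second came without eMC empty 4 (1490) or 5 (1586); in the last, leaving out CDS tumor 2 gave 3377 and eMC CIC-DUX4 5, 6 or 7 1097, 1217 or 1258. The replicate number as a block, used only for numbers found in both groups, gave 7413 genes in CDS tumors against eMC CIC-DUX4, 6147 and 2034 in the first 2 comparisons, and 14 lists in CDS tumors against eMC empty. Correlations of arrays with the same number, after removing group means, were 0.38, -0.19 and 0.38 in eMC CIC-DUX4 and eMC empty. After quantile normalization they were -0.00074, -0.0078 and 0.0048. These 3 pairs are too few to show whether the numbers pair the samples. CDS and ES tumors share no numbers. Genes higher in both eMC CIC-DUX4 (against eMC empty) and CDS tumors (against ES tumors) were 270 after quantile normalization and 482 with no filter (405 by chance), above chance where the deposited count was below it; genes lower in both were 140 and 29 (35.3 by chance). Genes shared by eMC CIC-DUX4 and CDS tumors against eMC empty were 590 after quantile normalization and 689 on average with the controls split. With fry, which asks another question, adjusted p was 0.334 for cell cycle, 0.215 for skeletal muscle, 0.159 for hypoxia (upward) and 0.179 for interferon genes in eMC CIC-DUX4 against eMC empty, 0.0616 for interferon genes in CDS tumors against eMC empty, 0.0760 for cell cycle genes in CDS against ES tumors, and 0.205 for macrophage and 0.440 for skeletal muscle markers in CDS tumors against eMC CIC-DUX4. Among the list calls ended by other settings were interferon response with the block (0.0609) or median scaling (0.107) in eMC CIC-DUX4 against eMC empty, and, in CDS tumors against eMC CIC-DUX4, interferon response with median scaling (0.0730) and Wnt genes with the block (0.137) or the mean of all probe sets (0.0933). Counts of genes and lists stayed within 1.5 times of those reported under all settings run and not named here. On simulated data, at a change of 1 log2 unit, 10.4, 1.49, 7.46 and 2.99% of changed genes were called as deposited (in the order above) and 50.7, 19.4, 14.9 and 19.4% after quantile normalization. At 4 units they were 62.1, 47.0, 59.1 and 48.5%, and 100.0, 100.0, 95.5 and 100.0%. This simulation left out the differences between the arrays' distributions. In it, 2.17 to 4.84% of the calls were false as deposited and 1.19 to 6.45% after quantile normalization. With those distributions and no changed gene, eMC CIC-DUX4 against eMC empty gave 5738 higher and 364 lower calls as deposited, all false. The comparisons of CDS tumors gave 0 calls each in that case.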

Other observations

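Of the tests in this part, the covariate for RNA quality and the counts over other splits of the samples were fixed before their results were seen; the comparison of distributions, the spike controls, the share of transduced cells, the host cells and the carry-over were chosen after. The limits for the share of transduced cells and for the carry-over were made stricter after a first version had come out in favour of both explanations, and the test on Etv4 and Crh was added after their values were seen.

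Some genes were higher in eMC CIC-DUX4 than in both the cells with the empty vector and the CDS tumors. Stmn2 rose by 5.90 ± 0.75 (SE; quantile 4.01 ± 0.16) against eMC empty (n = 4 each) and was at least 44.0-fold lower in CDS tumors (-8.70 ± 0.77, n = 6). For Dkk2 (at least 12.1-fold and 25.6-fold) these values were 6.39 ± 0.30 and -8.14 ± 0.77 (quantile 3.72 and -7.67), and for the cartilage gene Hapln1 (at least 6.09-fold and 12.9-fold) 5.90 ± 0.31 and -6.66 ± 0.78 (quantile 3.41 and -5.42). Of the 93 genes higher in eMC CIC-DUX4 and in both tumor comparisons, the secreted growth factor Bmp4 was higher by 1.74, 2.24 and 8.64 and Bmp5 by 1.01, 5.22 and 7.53 after quantile normalization, in the order eMC CIC-DUX4 against eMC empty, CDS tumors against eMC empty and CDS against ES tumors. By the dips of the dimmer group Bmp5 was at least 2.31-fold, 12.5-fold and 45.2-fold higher, and Bmp4 at least 123-fold in the last. The matrix glycoprotein gene Sparcl1 was higher by 3.82, 4.75 and 1.23, and Cox6b2, the testis form of a cytochrome oxidase subunit, by 3.80, 8.54 and 8.56 (at least 4.42-fold and 48.3-fold in the first 2).

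Of 19 DUX4 and Dux cleavage-stage genes, 9 were on the array and 0 were bright enough to be tested; each lay above the dip on at most 1 array. Hba-a1 had a mean log2 signal of 14.02 in CDS tumors, 13.52 in ES tumors, 8.56 in eMC CIC-DUX4 and 4.27 in eMC empty. The 3 probe sets of Mycn parted: the one that fell in eMC CIC-DUX4 was at 12.30 ± 0.39 in CDS tumors (SD, n = 6) and 12.40 ± 0.36 in ES tumors (n = 6), while the other 2 were at 5.48 ± 2.15 and 3.58 ± 0.85 in CDS tumors and at 12.90 ± 0.40 and 8.38 ± 1.04 in ES tumors.

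In eMC CIC-DUX4 against eMC empty, 5733 genes were called higher and 570 lower as deposited. Unchanged groups simulated with the distributions of the real arrays gave 5738 higher and 364 lower calls as deposited and 0 after quantile normalization, so the different distributions are a candidate explanation of the excess of higher calls. A general rise of transcription per cell may add to it. The hybridisation spike controls (18 probe sets) cannot decide this. They averaged 10.34 ± 0.13 in eMC CIC-DUX4 and 11.86 ± 0.16 in eMC empty (SD, n = 4 each). A different hybridisation could give this difference of -1.52 (exact permutation p = 0.0286) too. The spikes did not follow the fusion, being 11.91 ± 1.07 in CDS tumors and 10.36 ± 0.26 in ES tumors.

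Of the CIC target genes higher in CDS tumors than in eMC empty, 13 were not called higher on both scales in eMC CIC-DUX4. A small share of transduced cells, each at tumor levels, could give this, and a share of 2.75% followed from Vgf, Etv1 and Etv5 (1.44 to 4.75%). The observed signals lay a median of 0.214 log2 (SD 2.48 over genes) above those this share predicts, 6 of 13 within 1 log2 and 5 under the prediction, which decides nothing. Of 4 genes under the predicted signal on every eMC CIC-DUX4 array, Ccnd1 (12.75 against 13.53 predicted) and Ccnd2 (12.86 against 13.88) were below their level in eMC empty too (13.37 and 13.75), a high baseline that decides nothing; Etv4 was under it by -1.90 at the smallest (SD of the arrays 2.21) and Crh by -2.39 (SD 2.01); on the 3 arrays with a dip the gaps were -6.27 and -6.42, and replicate 6 leaves the question open. Host cells in the tumors might carry these genes, but all 13 were called higher in CDS than in ES tumors, by a median of 3.80 (SD 2.94) against at most 1.40 for a host marker list; the spread keeps this open, and a need for longer expression of the fusion was not tested.

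Cartilage genes higher in CDS than in ES tumors (10 genes) could be carried over from the mesenchymal cells; 4 of them (Col2a1, Col9a1, Col9a2 and Comp) were called higher in CDS tumors than in eMC empty on both scales and 9 had a higher mean there, with a median of 2.55, which leaves carry-over open for the rest. With the 3′ excess of Actb as a covariate for RNA quality, the median was 6.29 against 5.16 without it. Still called were 8 of 10 genes, and the list's adjusted p (limma camera) was 0.000114. This fit cannot exclude RNA quality. The excess was higher in every CDS tumor (0.310 to 1.28) than in every ES tumor (0.173 to 0.306), so it moves with the group. The origin of the tumors, another type of tumor or cell, stays among the open explanations and was not tested.

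Other splits of the same arrays were counted, the real split included. For eMC CIC-DUX4 against eMC empty, 1 of 35 splits gave as many genes as deposited (6303; highest other 0) and 1 after quantile normalization (1590; highest other 0). For CDS tumors against eMC empty 1 of 100 splits did (2518; highest other 2233), and 1 after quantile normalization (4533; 0); for CDS against ES tumors 1 (2564; 143) and 1 (4083; 1819). For CDS tumors against eMC CIC-DUX4, 2 of 100 did (2202; highest other 4720, the split of CDS tumors 2 and 4 with the eMC CIC-DUX4 arrays from the other CDS tumors, which gave 0 after quantile normalization and points to a structure of the array distributions), and 1 after quantile normalization (4575; 559). By these shares, few other divisions of the arrays reached the counts of genes (1 of 35 is the lowest share possible in the first). A split that mixes the groups puts their difference into the spread, so its fewer calls show only that the groups differ. In CDS tumors against eMC CIC-DUX4, as deposited, another split gave more. The splits do not show whether the eMC arrays came from separate cultures. They do not exclude the array distributions as the source of the counts either. With these distributions and no changed gene, eMC CIC-DUX4 against eMC empty gave 5738 higher calls as deposited. The same simulation gave 0 calls for CDS tumors against eMC empty and against eMC CIC-DUX4. Other groupings of the same arrays gave 2233 and 4720 there. The first of these put CDS tumors 1, 2, 3, 4 and 6 with eMC empty 7 and keeps much of the real grouping. These 3 deposited counts are therefore not taken alone to show that genes changed. For the number of lists a chance division cannot be excluded. As many as the 8 lists of eMC CIC-DUX4 against eMC empty came in 4 of 35 splits (highest other 9). For CDS tumors against eMC empty 20 of 100 gave as many as the 9 lists (13). For CDS against ES tumors 42 of 100 gave as many as the 7 (13), and for CDS tumors against eMC CIC-DUX4 21 of 100 as the 8 (11).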
